A study of Mus musculus with 2 samples.

How the data were processed

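Expression was measured with 2 Affymetrix whole-genome mouse arrays, 1 for vehicle-treated and 1 for PP1-treated primary osteoblasts. Per the labels' protocols, total RNA was extracted with Trizol and turned into biotinylated cRNA by the array maker's standard procedure. The values used here are the deposited array signals, a linear intensity for each probe set, that is, for each group of short probes against 1 transcript. They were made with MAS5, the array maker's summary method, per the submitters' processing notes, and its version and target scaling are not given in the sources used here. The file held 45101 probe sets, of which 64 were control probe sets and 45037 were not. The range of the values, from 0.0324 to 9434 on the DMSO array and from 0.0206 to 7989 on the PP1 array, is that of a linear scale. The median over non-control probe sets was 29.7 on the DMSO array and 20.0 on the PP1 array.

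Probe sets were named through the platform annotation, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCm38.p6, used for names only. A single gene was given for 34945 probe sets, several genes for 932 and none here for 9160 non-control probe sets, and the gene identifier matched the table for 34741 of those with 1 gene. No genome coordinates are given, because the sources used here name no build. Probe sets with several genes, and those unnamed here, entered no gene-level result.

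The PP1 array was multiplied by 1.68 so that both arrays had the same mean over non-control probe sets after trimming 2% at each end. The trimmed means as deposited were 158.1 on the DMSO array and 94.1 on the PP1 array. Scaled signals below 31.7, the median of all non-control probe sets on both arrays, were set to that floor, and log2 was taken. Each gene was represented by its probe set with the highest mean log2 signal. A gene counted as measured when that probe set was above the floor on at least 1 array, which held for 12111 of 18194 genes. The log2 ratio is PP1 minus DMSO, and a ratio with 1 array at the floor is a lower bound on its size.

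Each group is 1 array, so there are no replicates, no test between the groups was possible and no p-value is given. The number of arrays limits the precision. In place of a replicate error, the spread of the log2 ratio between different probe sets of a gene was computed, with an SD of 0.41 over the 4745 genes that had 2 or more probe sets above the floor on both arrays. It covers error between probe sets on these arrays, and not variation between cultures. Genes were counted at 2-fold or more in each direction.

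Before the data were examined, 38 gene lists and 11 lists of cell type markers were fixed. For each list with at least 5 measured genes, 10000 random lists of the same size were drawn, matched in 10 bins of mean signal. A list is said to stand apart when its median log2 ratio lies outside the central 95% of the medians of its random lists. The percentile describes these 2 arrays and is no test of the treatment.

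Genes are named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes that reach 4 times the floor on at least 1 array and whose probe sets above the floor all go the same way. A gene with only 1 probe set above the floor meets the last condition by default. The rule adds up to 4 genes per list by size of the log2 ratio, and 23 genes chosen by name for their part in Src, interleukin-6, IGF and bone biology, of which 18 were measured. Lyn, Runx2, Spp1, Bglap and Gapdh had no measured value under these names. This gave 215 genes, and the text names a part of them. Other names were chosen after their values were seen, as stated where they appear.

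The steps were first tested on simulated data made from the DMSO array, with noise of SD 0.4 on the log2 scale, an array scale of 0.6 and 200 changed genes. Over 11927 measured genes, the scale was recovered as 0.620. Of 25 genes made 3-fold higher, 22 were called 2-fold higher, and of 25 made 3-fold lower, 21 were called 2-fold lower. All 25 genes were called at 4-fold in each direction, and 151 of 11654 genes that had not been altered were called too. A list made 1.3-fold higher lay at percentile 100, and 3 of 46 other lists stood apart. The 200 changed genes all had a DMSO signal of at least 4 times the floor, so the recovery rates do not cover dimmer genes. The noise was the same at every signal. Between the real arrays the SD of the log2 ratio reached 0.58 in a dim signal bin, where more unaltered genes may be called.

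Alternatives planned beforehand were the values as deposited, centring on the median, a loess fit on mean signal, no floor, a floor at the 75th percentile, the median over a gene's probe sets, leaving out probe sets marked as shared between transcripts, fold thresholds of 1.5 and 3, and random lists not matched on signal. Scaling to the bacterial hybridization controls was added after the data had been seen. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.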

Results

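The data are expression profiles of primary osteoblasts, the bone-forming cells, grown from the calvaria (the skull vault) of 7-day-old CD1 mice. The cells were kept without serum for 24 h and then given either the vehicle DMSO or 2 µM PP1, an inhibitor of the tyrosine kinase c-Src and its relatives, for 24 h. The comparison asks which transcripts differ between the PP1 and the DMSO culture. The arrays do not measure kinase activity, so the part of c-Src in a difference is not shown. Markers of other cell types were present too, such as the macrophage marker Lyz1 with a signal of 5742 on the DMSO array. There was 1 array per condition and no replicate, so every value below describes these 2 arrays.

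With PP1, the interferon response was the list that stood highest, with all 22 measured genes above 0. The complement and acute phase list (10 of 13 genes above 0), the NF-kB target and chemokine list (17 of 23) and the cholesterol synthesis list (18 of 20) stood apart as higher too. Among genes well above the floor whose probe sets went the same way, the lowest ratio was that of Ptgs2, the inducible enzyme of prostaglandin synthesis, followed by Fam20a, Sertad4 and Ces5a. Fam20a, Sertad4 and Ces5a each had only 1 probe set above the floor. Connective tissue growth factor (Ccn2) was 5.80-fold lower, and the lists of SRF and actin genes (17 of 22 below 0), YAP and TEAD targets (12 of 17) and MAPK feedback genes (16 of 26) stood apart as lower, the latter 2 not under every alternative. Among single cytokines, Il6, Lif and Tnfsf11 (RANKL) were each more than 2-fold lower, the latter 2 from dim signals, while the equally dim Il34 was 3.02-fold higher. Neither the interleukin-6 family list nor the list of osteoblast signals to osteoclasts stood apart. Cell cycle genes, and Src itself by its brighter probe set, lay close to the bulk of genes.

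In numbers, 360 of 12111 measured genes were at least 2-fold higher with PP1 and 188 were at least 2-fold lower, while 9936 genes (82.0%) lay within 1.5-fold. These counts hold after scaling both arrays to the same trimmed mean. As deposited, the PP1 array was dimmer, and the counts were 50 higher and 2877 lower. Scaled to the bacterial hybridization controls, an option added after the data had been seen, they were 35 higher and 3774 lower. The median of all genes moved by -0.71 and -0.80 in those settings, so that every direction given below is relative to the bulk of genes. Of the 114 higher genes with several probe sets above the floor, 99 had all of them on the same side, as did 58 of the 81 lower genes, against 2678 of 5487 measured genes of this kind. Part of this contrast is built in, because the 2-fold genes were picked for a large ratio and most measured genes lay within 1.5-fold.

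**Figure D1:**
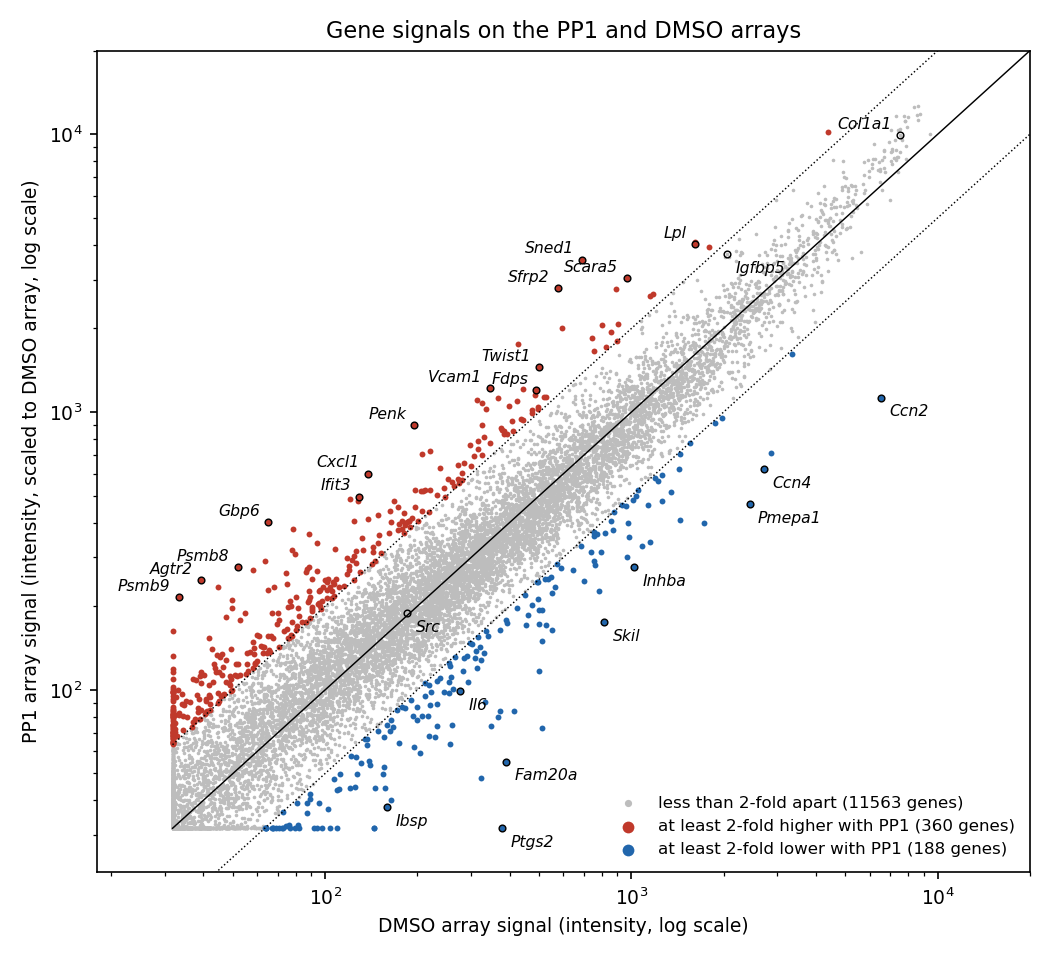
Signal of each of 12111 measured genes on the DMSO array (x axis, intensity, log scale) and on the PP1 array (y axis, intensity scaled to the DMSO array, log scale), with values below the floor of 31.7 drawn at the floor. The solid line marks equal signals and the dotted lines 2-fold, with 360 genes (red) at least 2-fold above and 188 (blue) at least 2-fold below; open circles mark genes named in the text.

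Among single genes, Ptgs2 had a signal of 377 with DMSO and was under the floor with PP1, which puts it at least 11.9-fold lower; its other probe set gave a log2 ratio of only -0.33. Fam20a, a regulator of kinases in the secretory pathway, was 7.08-fold lower, and Sertad4 was 6.96-fold lower. Ccn2 was the brightest of the 12 lowest genes, with a signal of 6535 against 1126, or 5.80-fold lower. Pmepa1 and Skil, both feedback inhibitors of TGF-beta signalling, were 5.21-fold and 4.65-fold lower, and the NADPH oxidase Nox4 was 4.70-fold lower. All 3 probe sets of Pmepa1 were lower, with log2 ratios from -2.79 to -2.17. At the other end, the immunoproteasome subunits Psmb9 and Psmb8 were 6.51-fold and 5.32-fold higher, from signals of 33.2 and 51.9 with DMSO. The angiotensin receptor Agtr2 was 6.30-fold higher (from 39.4), and the guanylate-binding protein Gbp6 was 6.18-fold higher (from 65.2). The Wnt-binding protein Sfrp2 was 4.87-fold higher, the matrix protein Sned1 5.11-fold, the opioid precursor Penk 4.60-fold and the transcription factor Osr1 4.66-fold (from 58.0). The DMSO signals given for these higher genes are close to the floor of 31.7, so their folds are imprecise. Of the higher genes named here, only Gbp6 had more than 1 probe set above the floor. Fam20a, Sertad4, Ccn2 and Skil likewise rested on 1 each.

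Of 47 lists with a percentile, 16 stood apart as higher and 5 as lower, where 2.35 would do so by chance if the genes of a list were unrelated. Lists share genes, such as Vcam1 and Lpl. With 1 array per group, the number that would stand apart between cultures treated alike is unknown. The interferon response list had the highest median, with a log2 ratio of 0.88 over 22 measured genes, all of them above 0 and 9 at least 2-fold higher. Its members include Psmb9, Ifit3 (1.94) and Stat2 (1.72). In the complement and acute phase list (median 0.60), the proteases C1s1 (1.77) and C1ra (1.41), properdin (Cfp, 2.09, but 0.33 by its other probe set) and factor B (Cfb, 1.31) were higher; C1qb (-0.76, its 3 probe sets from -1.16 to -0.17) and C1qa (-0.56), named after their values were seen, were lower. The list of NF-kB targets and chemokines had a median of 0.37. In it the neutrophil chemokines Cxcl1 (2.12, its 3 probe sets from 0.58 up) and Cxcl5 (1.83) and the adhesion molecule Vcam1 (1.82) were at least 2-fold higher, against the much lower Ptgs2.

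Both lipid lists stood apart as higher, and so did the 5 adipocyte markers (median 0.55), of which Lpl is also a lipid storage gene. The cholesterol synthesis list had a median log2 ratio of 0.38, with 18 of 20 genes above 0 and Fdps, which makes farnesyl diphosphate, 2.46-fold higher. In the fatty acid and lipid storage list (median 0.34, 16 of 18 above 0), lipoprotein lipase (Lpl) stood at 1.32, the phosphatidate phosphatase Lpin1 at 1.03 and the citrate lyase Acly at 0.94 (its 3 probe sets from 0.18 to 1.36). The FOXO and starvation list had a median of 0.43, with 15 of 20 genes above 0. The sestrins Sesn3 (1.16) and Sesn1 (0.85) and the autophagy gene Gabarapl1 (0.91) were higher, and the transcription factor Klf2 (-0.93) was lower. The list of p53 targets and cell cycle inhibitors had a median of 0.21, with 17 of 23 genes above 0 and the CDK inhibitor Cdkn1c at 1.94.

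The 5 lists that stood apart as lower held signalling, cytoskeletal and stress genes. Immediate early and MAPK feedback genes had a median of -0.38 over 26 genes, with 10 above 0 and 10 at least 1.5-fold lower, among the latter the ERK phosphatase Dusp5 (-2.03), Myc (-1.02) and Spry1 (-0.94). The YAP and TEAD target list had a median of -0.26, with 5 of 17 genes above 0, and besides Ccn2 its lowest members were tissue factor (F3, -1.43), Ccn1 (-0.99) and Ajuba (-0.83). Of 22 genes of the SRF and actin list, 17 were below 0 (median -0.23), including the smooth muscle genes Actg2 (-1.54) and Cnn1 (-1.37, a bound, as it was at the floor with PP1) and the cofactor Fhl2 (-1.08). Actg2 and Cnn1 are also smooth muscle and pericyte markers, a list that did not stand apart (median -0.11, 7 of 9 genes below 0, 3 at least 2-fold lower, with Cspg4 at -1.74 and, by its other probe set, -0.68). The ATF4 and unfolded protein list had a median of -0.27 with 18 of 27 genes below 0. Its lowest members were the folate enzyme Mthfd2 (-1.24, or -0.46 by its other probe set) and the amino acid transporter Slc7a5 (-1.06). Shmt2 (-0.93, its 4 probe sets from -1.29 to 0.13) and asparagine synthetase (Asns, -0.89) followed. In the BMP and TGF-beta list 22 of 29 genes were below 0 (median -0.20), with activin A (Inhba) at -1.88 and, against them, the co-receptor Tgfbr3 at 1.05 and Id4 at 1.05.

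**Figure D2:**
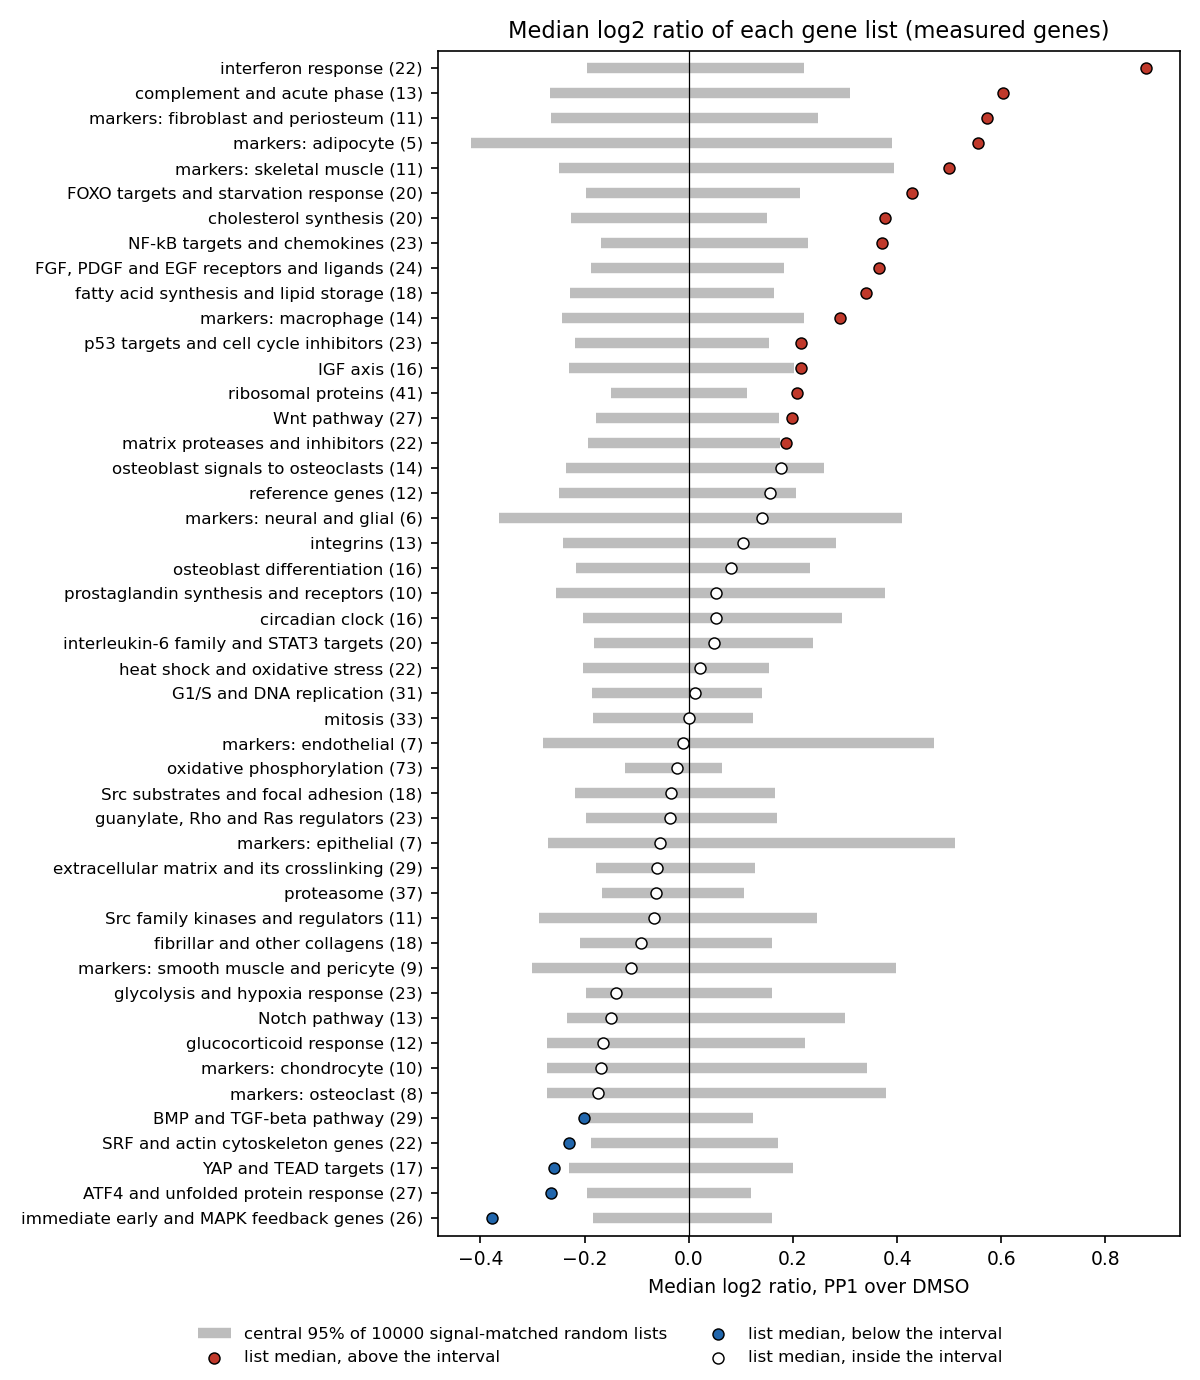
Median log2 ratio (x axis, PP1 over DMSO) of each of 47 gene and marker lists, with the number of measured genes in brackets; grey bars span the central 95% of medians of 10000 random lists matched on signal. The interferon response (0.88) lies farthest above its bar and immediate early and MAPK feedback genes (-0.38) farthest below 0; directions are relative to the bulk of genes.

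The interleukin-6 family did not stand apart as a list, with a median of 0.05 over 20 genes, and its members went both ways. Il6 was 2.79-fold lower (signal 275.7 against 98.9), Lif 2.30-fold (74.2 against 32.2, close to the floor) and Clcf1 2.29-fold. The 3 probe sets of Clcf1 ran from -1.19 to 0.48. The receptors were not lower: Lifr stood at 1.00 (0.27 by its other probe set), the shared signal chain Il6st at 0.84 with all 4 probe sets from 0.84 to 1.62, and Il6ra at 0.04. The IGF axis stood apart as higher, with a median of 0.21 and 13 of 16 genes above 0. Its highest members were the binding proteins Igfbp5 (1.80-fold, signal 2049 against 3697), Igfbp3 (0.72) and Igfbp4 (0.62), and Igf1 was at 0.46. The other probe set of Igfbp5 gave 2.31, and the 6 of Igfbp4 ran up to 2.66, so the sizes for these genes depend on the probe set. For Igf2 the direction did too, with 0.32 by its brighter probe set and -0.99 by the other.

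The 16 measured osteoblast differentiation genes did not move as a group (median 0.08). For 6 names of that list no gene was found in the probe set annotation used here, which does not show that the array lacks them. Runx2, Spp1 and Bglap, which had been chosen by name, were not among the measured genes, so the median does not speak for them. Bone sialoprotein (Ibsp) was 4.22-fold lower, from a signal of 159.1 to 37.7, close to the floor. Alkaline phosphatase (Alpl) was at 0.37, the transcription factor Sp7 at -0.43, and the collagen genes Col1a1 and Col1a2 at 0.39 and 0.52, though the 3 probe sets of Col1a2 ran from -0.91 to 0.52. Of the signals that osteoblasts send to osteoclasts, Tnfsf11 (-1.16) and its decoy receptor Tnfrsf11b (-1.01, or -0.63 by its other probe set) were both lower. Tnfsf11 rested on 1 dim probe set, with a signal of 106.5 against 47.6. Csf1 was at -0.02 (up to 1.42 among its 4 probe sets) and Il34 at 1.60, from a dim signal of 44.2 with DMSO. The 14 genes of that list had a median of 0.18. Collagens (median -0.09, 18 genes) and the wider matrix list (-0.06, 29 genes) did not stand apart, although tenascin C (Tnc, -1.39) and Col5a3 (-1.11) were each more than 2-fold lower. Elastin (Eln) was at -1.68 by its brighter probe set and -0.07 by the other, and the median over both ended its 2-fold difference (-0.92). The brightest genes were shifted upward as a class: 33 genes with a DMSO signal above 7000 had a median log2 ratio of 0.37, a range that includes Col1a1 and Col1a2.

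Transcripts of the kinases that PP1 inhibits lay close to the bulk of genes by their brighter probe sets. Src was at 0.03 by its brighter probe set and 1.08 by the other, Fyn at 0.05 and Yes1 at -0.26, and the probe sets of Fyn and of Yes1 went both ways. The Src family list (median -0.07, 11 genes) and the focal adhesion list (-0.03, 18 genes) did not stand apart. Neither did mitosis (-0.00, 33 genes) or G1/S and DNA replication (0.01, 31 genes), and cyclin D1 (Ccnd1) was at 0.07. Of the 13 Notch genes, 9 were below 0 and 4 at least 2-fold lower: Heyl (-1.82), Nrarp (-1.71, a bound), Hey1 (-1.33) and Hes1 (-1.17). The median of the list was -0.15 and inside the range of its random lists. Growth factors went both ways within 1 list: Hbegf (-1.88) and Ereg (-1.34) were lower, and Vegfd (1.45) was higher, while the list median of 0.36 stood apart, with 17 of 24 genes above 0. Pdgfb was at -1.78 by its brighter probe set and 0.10 by the other. The Wnt list (median 0.20, 20 of 27 genes above 0) held Sfrp2 (2.28) and Frzb (1.37, a lower bound) on one side and Ccn4 (-2.13) and Wnt4 (-1.33, or -0.43 by its other probe set) on the other. Matrix proteases (0.19, 12 of 22 genes above 0) likewise held Adamts9 (1.42, its 3 probe sets from 0.73 to 1.57) and Plaur (-1.27).

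**Figure D3:**
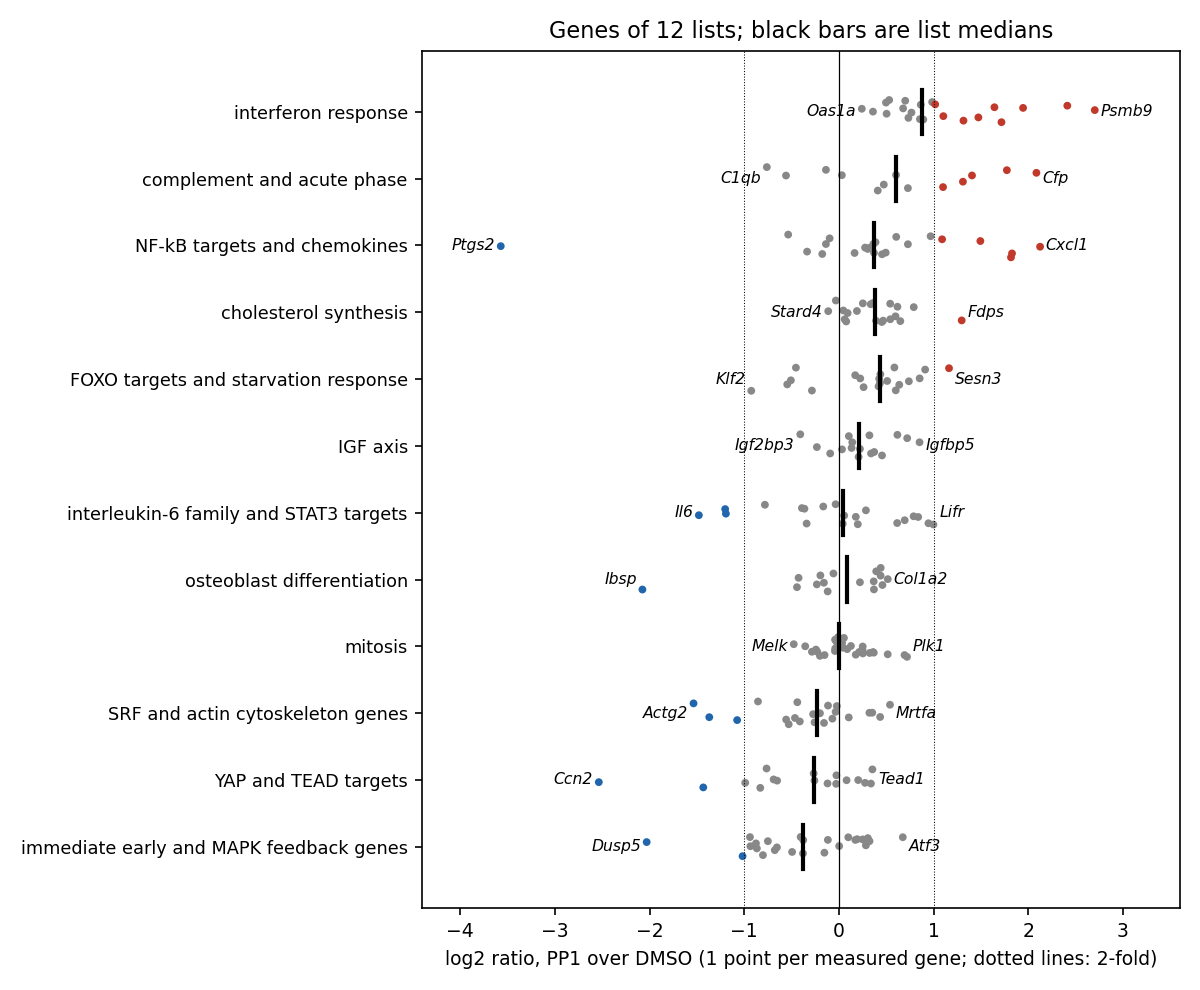
Log2 ratio (x axis, PP1 over DMSO) of each measured gene of 12 lists (rows), with list medians as black bars, genes at least 2-fold higher in red and at least 2-fold lower in blue, and the lowest and highest gene named. All 22 interferon genes lie above 0, whereas the interleukin-6 family runs from Il6 (-1.48) to Lifr (1.00); directions are relative to the bulk of genes.

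Markers of other cell types also differed. Fibroblast and periosteum markers had a median of 0.57, with 9 of 11 genes above 0, the ferritin receptor Scara5 at 1.66 and the transcription factor Twist1 at 1.54. Adipocyte markers stood at 0.55 (5 genes, all above 0, with Pparg at 0.65) and skeletal muscle markers at 0.50 (11 genes, with Des at 1.43). The muscle markers with the largest ratios were dim. Des, which is also a smooth muscle and pericyte marker, went from a signal of 39.4 to 105.9, and Myog and Myod1 were at the floor with DMSO. Macrophage markers had a median of 0.29, with 10 of 14 genes above 0, Mrc1 at 1.11 and Cd68 at 0.73. Markers of osteoclasts (-0.17, 8 genes), cartilage (-0.17, 10 genes) and endothelium (-0.01, 7 genes) did not stand apart, nor did neural (0.14, 6 genes) and epithelial markers (-0.05, 7 genes). The 4 measured osteocyte genes had a median of 0.11 and the 2 blood genes 0.18, too few for a percentile.

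The ribosomal protein list stood apart as higher (0.21, 29 of 41 genes above 0), and the 12 reference genes had a median of 0.16, with Hprt at -0.51 and B2m at 0.57. As a sign of RNA quality, the log2 ratio of 3' to 5' control signals differed between PP1 and DMSO by -0.51 for Gapdh, by -0.34 for pyruvate carboxylase (Pcx) and by 0.14 for Actb.

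Of the 21 lists that stood apart, 11 did so under all 9 alternative settings, and the skeletal muscle markers under the 8 that could be run for them; the Wnt, BMP and TGF-beta, matrix protease, YAP, IGF, ribosomal, fatty acid, MAPK feedback and macrophage lists did not under at least 1. Conversely, the Notch, integrin, osteoblast differentiation, heat shock, prostaglandin and reference gene lists stood apart under at least 1 alternative, and Dusp5 was left with a bound near 0 by a floor at the 75th percentile.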

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

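The tests of explanations in this part were all chosen after the results were seen. Data outside the gene-level comparison also differed between the arrays. Among 2372 probe sets above the floor with no gene name here, 59 were at least 2-fold higher with PP1 and 27 at least 2-fold lower. Among 589 probe sets that match several genes, the counts were 23 higher and 7 lower.

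The control probe sets showed a difference of scale. As deposited, the trimmed mean of mouse probe sets was lower with PP1, by -0.75 on the log2 scale, whereas 18 probe sets for bacterial RNA added at hybridization had a median log2 ratio of 0.0935 (SD 0.20 between probe sets). A difference in scanner gain, or 1 factor applied to the whole array, is argued against, because it would have lowered these controls by the same -0.75. Less labelled mouse cRNA on the PP1 array may account for it, and so might a lower mRNA content of the treated cells. These cannot be told apart, because 0 of 27 poly-A control probe sets, which report RNA added before labelling, lay above the floor. Any statement on absolute transcript levels depends on the answer.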

How the results depend on the processing

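Of the 21 lists that stood apart, 11 did so under all 9 alternatives and the skeletal muscle markers under the 8 that could be run for them, and none of the 21 changed direction against its random lists. List medians and log2 ratios here are shifted so that the median of all genes equals the 0.0092 of the main setting. Centring on the median changed the side of no list, and the counts stayed within 1.5 times under that centring, loess, the median over probe sets and the omission of shared probe sets. With loess, 289 of the 360 higher and 174 of the 188 lower genes were still at least 2-fold. At least 2-fold higher and lower were 50 and 2877 genes as deposited and 35 and 3774 scaled to the bacterial controls, which moves all genes by 1 factor. They were 2065 and 1522 with no floor, where signals near background enter, and 111 and 84 with a floor at the 75th percentile, where dim genes drop out. At fold thresholds of 1.5 and 3 they were 1282 and 893, and 60 and 42.

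For lists that crossed the edge of their random range the cause was not tested. As deposited, Wnt (0.17) and YAP (-0.16) no longer stood apart and Notch (-0.41) did. Scaled to the bacterial controls, chosen after seeing the data, Wnt (0.18) and YAP (-0.16) did not, and Notch (-0.39) and osteoblast differentiation (0.22) did. With loess, BMP and TGF-beta (-0.10), Wnt (0.17), matrix proteases (0.11) and ribosomal proteins (0.0370) did not. With no floor, BMP and TGF-beta (-0.20), Wnt (0.13) and macrophage markers (0.20) did not. With the floor at the 75th percentile, BMP and TGF-beta (-0.15), YAP (-0.0705) and macrophage markers (0.265) did not, and integrins (0.53) and osteoblast differentiation (0.42) did. With the median over probe sets, BMP and TGF-beta (-0.12), IGF (0.12), Wnt (0.15), fatty acid (0.16), MAPK feedback (-0.17) and matrix protease (0.14) lists did not, and reference genes (0.22) did. Against random lists not matched on signal, IGF (0.21), Wnt (0.20) and matrix proteases (0.19) did not. Without shared probe sets, IGF (0.20), macrophage markers (0.20), matrix proteases (0.17) and ribosomal proteins (0.12) did not, while heat shock (0.27) and prostaglandin (-0.32) lists did; the prostaglandin list was at 0.05 in the main setting. Of 96 named genes at 2-fold or more, none was measured on the other side of 0 under any alternative. At the 75th percentile floor, Dusp5 (0.0228) and Acan (0.00247) lie above 0 only through the shift: with PP1 at that floor and DMSO just over it, both ratios are bounds close to 0. That floor also turns the ratios of genes dim on 1 array, such as Psmb9, Psmb8, Agtr2 and Il6, into bounds below 2-fold. Lists with fewer than 5 genes left above that floor have no percentile there.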

Other observations

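The tests of explanations in this part were all chosen after the results were seen, as were the gene families and the genes named from them. Families of genes that share the start of their symbol were scanned for those with at least 10 measured members. Of 139 families, 8 lay above and 9 below the central 95% of their random lists, where 6.95 would lie outside by chance if the genes of a family were unrelated. Genes with the symbol start Eif (46 genes), mostly translation initiation factors but also kinases such as Eif2ak1 (0.67), had a median log2 ratio of -0.30, with 34 below 0. Mitochondrial ribosomal proteins (Mrpl and Mrps, 76 genes) had a median of -0.22, with 59 below 0, and the Timm genes of mitochondrial import (14 genes) one of -0.35. Enzymes that methylate tRNA (Trmt, 15 genes) stood at -0.43, and all 13 small nucleolar RNA host genes (Snhg, median -0.46) were below 0, down to Snhg3 at -1.01. The other lower families were Zdhhc (-0.29), Naa (-0.29) and Ndufa (-0.22). The oxidative phosphorylation list fixed beforehand did not stand apart (-0.02, 73 genes), so these values do not extend to mitochondrial genes in general. Relative to the bulk of genes, the family medians stayed below 0 under all 4 other scalings tried, although with loess Zdhhc, Naa and Ndufa lay inside the range of their random lists, as Naa did when scaled to the bacterial controls.

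Of the higher families, aldehyde dehydrogenases (Aldh, 19 genes) had a median of 0.62, with 14 above 0 and 3 at least 1.5-fold lower, from Aldh1a3 at -1.57 (a bound, at the floor with PP1) to Aldh1a7 at 1.99. Poly-ADP-ribose polymerases (Parp, 11 genes) had a median of 0.45, with the interferon-induced Parp14 at 0.80. The others were Clec (0.41), Adam (0.34), Ccl (0.34), Cyp (0.33), Mmp (0.32) and Rps (0.23); Cyp lay inside the range of its random lists under all 4 other scalings, and Rps did with loess. A pair of families below the scan's size or naming rule was added by hand. Glutathione S-transferases had a median of 0.72 over 13 genes, of which 12 were above 0 and 6 at least 2-fold higher, led by Gstt3 (2.27). Genes with the symbol start H2 (9 genes), mostly histocompatibility genes, had a median of 0.60, with H2-D1 at 1.13. This median is the value of H2-DMb2, a lower bound, as it was at the floor with DMSO. The H2 genes lay inside the range of their random lists as deposited and scaled to the bacterial controls. The fixed heat shock and oxidative stress list did not stand apart (0.02, 22 genes). Each of these family medians stayed above 0, relative to the bulk of genes, under the 4 other scalings.

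The interferon response list (median 0.88) invites a search for its source. A larger share of macrophages in the PP1 culture is argued against as the whole cause, though not as a part of it. Macrophage markers, themselves apart as higher, had a median of 0.29, below that of the interferon list. The 95% bootstrap limits (-0.01 to 0.64) were drawn over marker genes and do not cover variation between cultures. The brightest macrophage markers, Lyz1, Lyz2, Ctss and Csf1r, had signals of 5742, 4892, 1845 and 1301 on the DMSO array. Their log2 ratios were 0.10, 0.36, -0.18 and -0.01, while Mrc1 (1.11), Cd74 (0.95), Cd68 (0.73) and Laptm5 (0.64) were higher. A shift tied to signal level is argued against as the whole cause, because after the loess correction the list still had a median of 0.79, outside the range of its random lists (-0.23 to 0.18). A response to PP1 of the cultured cells, of whichever type, stays open as a hypothesis. A difference between the 2 cultures that has nothing to do with PP1 stays open too. With 1 array per group, how far cultures treated alike would differ is unknown.

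The higher signals of ribosomal proteins may be a property of bright signals. Of 60 other genes with a DMSO signal above 5000, 49 were above 0, with a median of 0.22 against 0.30 for the 26 ribosomal proteins in that range (95% bootstrap interval of the difference -0.13 to 0.10). Of those 26 ribosomal proteins, 24 were above 0, against 5 of the 15 with a signal of 5000 or less. A change of ribosomal proteins as a class stays open: these 15 had a median of -0.21, but its 95% bootstrap limits (-0.29 to 0.23) include the 0.21 of the whole list. That list of 41 includes the 26 bright ones. Compression of the brightest signals on the DMSO array is consistent with the values of the other bright genes, and the loess correction, which removes a trend with signal, left a median of 0.0277 for the whole list, relative to all genes. Col1a1, Col1a2 and Eef1a1 lie in the same range, so their higher values share this doubt.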
